A study of Mus musculus with 8 samples.

How the data were processed

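RNA from the medial prefrontal cortex (mPFC) of mice was measured on 8 Affymetrix expression arrays. The mice carried a Cre-dependent ribosomal tag, and per the labels a canine adenovirus that delivers Cre recombinase (CAV2-Cre) was injected in a target region of mPFC axons, given there as NAC or VTA. A virus of this kind is taken up at axon terminals and carried back to the cell body, so the tag is switched on in mPFC cells that project to the injected target. The mPFC was dissected, and ribosomes bearing green fluorescent protein (GFP) were pulled down with a GFP-binding reagent, a method known as translating ribosome affinity purification. The labels give 4 groups of 2 arrays each: pull-down RNA after NAC injection, pull-down RNA after VTA injection, and unpurified input RNA of each. RNA was prepared with Trizol and a Qiagen kit and hybridised as biotinylated cRNA, per the labels. The labels do not state whether the 2 arrays of a group came from separate animals or pools.

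The deposited table holds 1 value on the log2 scale per probe set and array, for 41345 probe sets, and the values were used as the authors deposited them. Per the submitters' processing notes they were made with Transcriptome Analysis Console, whose version is not given there; the background correction, summarization and normalization settings are not given in the sources used here. The table's medians over all probe sets lay between 5.08 and 5.22 on the 8 arrays, which fits a scale already shared between arrays, so no further normalization was applied in the main comparisons. Such a scale assumes that arrays hold like amounts of RNA, and pull-down RNA can break that assumption, so other scalings were tried.

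Probe sets were named through the platform annotation supplied with the data. Of the 41345 probe sets, 23521 had 1 gene symbol, 1814 had several and 16010 had none. For 23328 of the 23521 the Entrez identifier was found, with the same symbol, in a RefSeq gene table of the mouse assembly GRCm38.p6, and 193 were not in it and kept the annotation's symbol. Only probe sets with 1 symbol were named. They covered 22180 genes, and each gene was represented by its probe set with the highest mean over the 8 arrays. A gene was tested where at least 2 of the 8 arrays exceeded that array's median over the named genes, which left 11712 genes. Among these, 393 genes had several probe sets bright enough to be tested; the probe sets of 25 of them were called in opposite directions in the averaged pull-down comparison, those of 16 genes in the VTA pull-down against its input, and none in the other comparisons. Of the sex-linked list, Xist, Kdm5d, Uty and Eif2s3y were below the filter, and Ddx3y had no probe set with 1 symbol. Xist lay at 5.46 to 6.01 on the NAC arrays and at 4.47 to 5.33 on the VTA arrays, near or under the array medians. The levels of Kdm5d, Uty and Eif2s3y overlapped between the targets.

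A linear model with a mean for each of the 4 groups was fitted to all 8 arrays with limma 3.58.1 in R 4.3.3, with moderated variances (lmFit and eBayes), so that all groups share 1 estimate of the spread. The model left 4 residual degrees of freedom, to which the moderation added 6.07. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the 11712 genes, and an adjusted p of 0.05 was the threshold. The 6 comparisons were pull-down minus input averaged over both targets, pull-down minus input for NAC and for VTA, VTA minus NAC pull-down, VTA minus NAC input, and the difference of enrichment, which is VTA pull-down minus VTA input less the same difference for NAC. The comparison of the pull-downs and that of the inputs share no arrays. Differences are given on the log2 scale with the standard error (SE) of the model, and group levels as mean ± standard deviation (SD) of 2 arrays. Values for arrays carry no read depth; their number limits the precision.

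There were 34 gene lists. They held markers of glutamatergic projection neurons, layer 2/3 intratelencephalic, layer 5 intratelencephalic, layer 5 pyramidal tract and layer 6 cells, GABAergic interneurons, striatal medium spiny neurons, astrocytes, oligodendrocytes, their precursors, microglia, endothelial cells, mural cells with fibroblasts, and blood cells. Other lists held immediate early genes, interferon and antigen presentation genes, receptors for monoamines and acetylcholine, for glutamate and for GABA, potassium and HCN channels, sodium and calcium channels, synaptic vesicle genes, postsynaptic scaffolds, axon guidance genes, neuropeptides, nuclear-encoded and mitochondrially encoded respiratory genes, cytosolic ribosomal proteins, replication-dependent histones, nuclear long noncoding RNAs, small nucleolar RNAs, olfactory receptors, sex-linked genes, and heat shock with unfolded protein genes. Lists with at least 3 measured members were tested, which left 32. Each was tested with limma's camera, which ranks a list against all other genes, with a preset correlation of 0.01 between genes and again with a correlation estimated per list. The second set test, fry, asks whether the genes of a list move on balance one way and does not compare them with other genes. Set p-values were adjusted by Benjamini-Hochberg over the 32 lists of a comparison. For the pyramidal tract markers, the mean of a list on each array was also compared between groups, with the standard error from the spread of the replicates. This comparison, which does not take genes as independent, and the comparison of levels with the array medians over all named genes were added after the data had been seen. Counts of members past the threshold are given over all genes tested and adjusted over the list alone.

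The groups, the comparisons, the filter, the lists, the alternatives and the rule for named genes were set before the data were examined. The rule took, for each comparison, the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold whose arrays did not overlap between the groups, leaving out predicted genes and families of small RNAs and receptors; where a direction had fewer, up to 5 genes were filled in by smallest p and are reported as not past the threshold. It also took up to 4 members of each list by smallest p, and a fixed set of cortical marker genes, receptors and controls. Gm10139 and 1700007K13Rik fall outside the rule and are named because so few genes passed the test of the difference of enrichment; they were chosen after their values were seen. Of the genes the rule takes by the size of their change, 1 immunoglobulin kappa segment is not named in the text. Many of the list members that it takes are not named either. A few further members of lists, gene families in the last part and second probe sets of named genes were likewise chosen after their values were seen.

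The alternatives were quantile normalization across the 8 arrays or within pull-downs and inputs separately, centring each array on its median, no filter or a filter at the 75th percentile of gene means, all probe sets tested singly, the mean of a gene's probe sets, moderation with an intensity trend and robust estimation or none at all, array weights, a fit on only the groups compared, the replicate number as a block, the pull-down and input of 1 number as a pair, other thresholds, and leaving out each of the 8 arrays in turn. A crossed pairing and a test without the genes that passed in the inputs were added after the data had been seen. The code was tested on simulated data for the comparison of the pull-downs, with 200 of the 11712 genes changed. It called 31 of 50 genes changed 1.5-fold, 45 of 50 changed 2-fold, 49 of 50 changed 3-fold and 50 of 50 changed 5-fold, and 8 of its 183 calls were false. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.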

Results

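Gene expression in mouse mPFC was profiled in ribosome-bound RNA pulled down from cells labelled by a Cre virus in NAC or VTA, and in the unpurified input RNA of the same tissue. Each of the 4 groups held 2 arrays, so the number of arrays limited the precision of every value. Because the labels do not say whether the 2 arrays of a group are separate animals, p-values measure only the spread between these samples, which the labels do not trace to animals. Correlations between arrays over all 41345 probe sets were 0.981 to 0.991 within groups (4 pairs) and 0.973 to 0.988 between groups (24 pairs). Probe sets are not independent replicates. The first principal component held 50.4% of the variance and separated the 4 pull-downs from the 4 inputs, and the second held 24% and separated NAC from VTA samples. The first NAC pull-down lay closest to the inputs among the pull-downs on the first component.

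The comparison of pull-down with input asked which transcripts the tagged ribosomes enriched, averaged over both targets. Rpl10a, which codes for a protein of the large ribosomal subunit, had the largest rise, 2.81-fold (log2 difference 1.49, SE 0.10, n = 4 pull-downs and 4 inputs). It went from 10.93 ± 0.02 to 12.08 ± 0.04 in NAC samples and from 10.11 ± 0.34 to 11.94 ± 0.01 in VTA samples (log2 mean ± SD, n = 2). Many, though not all, markers of cells that were not meant to carry the tag fell in the pull-downs. Mog, a myelin protein gene of oligodendrocytes, fell by 0.76 on the log2 scale, and Gad2, which codes for a GABA-synthesising enzyme of interneurons, fell by 0.76. Snord47, a small nucleolar RNA that resides in the nucleolus, fell by 3.20, from 8.07 ± 0.08 to 4.49 ± 0.23 in NAC samples. The lower level lay under the array medians over all named genes (5.86 to 5.98), so the size of that fall is not exact. The limma adjusted p (Benjamini-Hochberg) was 4.1e-05 for Rpl10a, 0.00041 for Mog, 0.00042 for Gad2 and 3.2e-07 for Snord47.

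Other genes with a large rise were Tma7, a translation machinery factor, at 1.30, Mettl7a3 at 1.28, Ywhah, which codes for a 14-3-3 protein, at 1.25, and the tubulin gene Tuba1b at 1.08. Below these came the mitochondrial complex III assembly gene Uqcc2 at 0.96, the mitochondrial ribosomal protein genes Mrpl54 and Mrpl42 at 0.96 and 0.89, Nol8 at 0.95 and the ATP synthase gene Atp5d at 0.91. The largest falls were those of Ptcd3 at -1.72, the Y RNA gene Rny3 at -1.50, Scarna10 at -1.43, the apoptotic protease gene Casp8 at -1.28 and Taf1d at -1.07. Next were the astrocytic thyroid hormone deiodinase gene Dio2 at -1.05, Havcr2 at -1.04, the oligodendrocyte gap junction gene Gjc3 at -1.04, Sft2d2 at -1.02 and Acss1 at -0.99. Several of these rested on 1 of a pair of probe sets. The second probe set of Ptcd3 differed by 0.00, that of Ywhah by 0.02 and that of Atp5d by 0.16. Of the others of Taf1d, 1 was also lower at -2.23 and 1 was at -0.40, which did not pass. That of Tma7 was at 1.13 and did not pass either. Pull-down levels of Casp8 and Taf1d lay under the array medians, as did that of Scarna10 with NAC and that of Havcr2 with VTA, so the sizes of their falls are not exact. Among cortical markers, the layer 5 transcription factor gene Fezf2 rose by 0.24, and Camk2a, a kinase gene of excitatory neurons, had -0.23. Gad1 fell by 0.37, and the astrocytic genes Aqp4 and Gfap by 0.67 and 0.44. Cx3cr1, a chemokine receptor gene of microglia, fell by 0.30, Foxp2 of deep layers by 0.30, the interneuron gene Pvalb by 0.21, and Drd1, the D1 dopamine receptor gene, by 0.78. The threshold was missed by Slc17a7 (-0.05), Cux2 (-0.12), Etv1 (0.16), Bcl11b (0.01), Sst (0.04), Mbp (-0.07), Cldn5 (-0.21), Fos (0.05), Arc (-0.11), Drd2 (-0.12) and Cxadr (-0.02). When each array was centred on its median the values of Camk2a, Foxp2 and Pvalb were -0.09, -0.17 and -0.07, and none of them passed. Fezf2 lost its call without the second NAC pull-down (0.21, limma adjusted p with Benjamini-Hochberg = 0.0701), the first NAC input (adjusted p = 0.0629) or the second VTA input (adjusted p = 0.0575).

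Glial, vascular and interneuron markers were lower in the pull-downs as groups. Of 17 oligodendrocyte genes, 15 fell and none rose (0 up and 16 down adjusted over the list alone; median -0.48), among them Mal (-0.79) and Cldn11 (-0.64). Of 19 microglial genes, 18 fell and none rose (18 down adjusted over the list alone; median -0.46), among them Csf1r (-0.62), Fcrls (-0.78), Ly86 (-0.69) and C1qa (-0.58). Of 22 GABAergic interneuron genes, 14 fell and 8 did not pass (16 down adjusted over the list alone; median -0.36), with Nxph1 at -0.67 and Erbb4 at -0.65. Of 18 astrocyte genes, 13 fell (13 adjusted over the list alone; median -0.27), with Slc1a3 at -0.62 and Gja1 at -0.59. Of 15 endothelial genes, 10 fell and 1, Egfl7 at 0.54, rose (11 and 1 adjusted over the list alone; median -0.37). Of 11 oligodendrocyte precursor genes, 6 fell (8 adjusted over the list alone; median -0.21), with Pdgfra at -0.82. Of 15 mural and fibroblast genes, 8 fell (9 adjusted over the list alone; median -0.31). With each array centred fewer passed: 13 oligodendrocyte, 12 microglial, 11 interneuron, 7 astrocyte, 6 endothelial, 4 precursor and 6 mural and fibroblast genes were lower, and 1 interneuron, 1 astrocyte and 1 endothelial gene were higher. The astrocyte median was then -0.13 and that of precursors -0.07. In camera, with Benjamini-Hochberg adjustment, the adjusted p was 1.0e-06 for oligodendrocytes, 5.2e-06 for microglia, 0.0031 for interneurons and for astrocytes, 0.026 for endothelial cells, 0.041 for oligodendrocyte precursors and 0.025 for mural cells and fibroblasts. None of these calls held with an estimated correlation, where the 7 values ran from adjusted p = 0.25 with an estimated correlation for oligodendrocytes to adjusted p = 0.39 with an estimated correlation for endothelial cells. The camera call of oligodendrocyte precursors was also lost without the first NAC pull-down (adjusted p = 0.0607), the second NAC input (adjusted p = 0.055) or the second VTA pull-down (adjusted p = 0.0609). That of mural cells and fibroblasts was lost without the first NAC pull-down (adjusted p = 0.0578) or the second NAC input (adjusted p = 0.0516).

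Projection neuron lists differed among themselves. Of 16 glutamatergic projection neuron genes, 2 rose and 4 fell (2 and 4 adjusted over the list alone). Their median was -0.06 and their mean -0.05, while camera ranked them above other genes (adjusted p = 0.55), and with each array centred the median was 0.08 and the split turned round, to 5 higher and 1 lower. Of 16 layer 5 pyramidal tract genes, markers of neurons that project out of the telencephalon, 6 rose and 1 fell (6 and 1 adjusted over the list alone; median 0.02, camera adjusted p = 0.02, and adjusted p = 0.34 with an estimated correlation). Chst8 rose by 0.67, Pou3f1 by 0.40 and Pcp4 by 0.38, and Cdh13 fell by 0.42. The median of this list was -0.01 without the first NAC input, and 0.16 with each array centred, where its counts were unchanged. Of 14 layer 2/3 genes, 8 fell (8 down and 1 up adjusted over the list alone; median -0.20; camera adjusted p = 0.16), and 3 were lower and 1 higher with each array centred. Of 13 layer 5 intratelencephalic genes, 1 rose and 2 fell (the same counts adjusted over the list alone; median -0.07; camera ranked the list upward, adjusted p = 0.58). Their median was 0.07 with each array centred, with 4 higher and 2 lower. Of 15 layer 6 genes, 1 rose and 7 fell (1 and 10 adjusted over the list alone; median -0.21; camera adjusted p = 0.28), but with each array centred 1 was higher and 1 lower. Of 9 striatal medium spiny neuron genes, 5 fell (5 adjusted over the list alone; 3 with each array centred; camera adjusted p = 0.23). The 1 measured gene of the blood cell list, Ptprc, fell by 0.46 (limma adjusted p with Benjamini-Hochberg = 0.017).

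Transcripts of respiration and of the ribosome were higher in the pull-downs, and small nucleolar RNAs were lower. Of 44 nuclear-encoded respiratory chain genes, 22 rose and none fell (26 and 0 adjusted over the list alone; median 0.21), with Ndufa1 at 0.77, Ndufa5 at 0.67 and Ndufb10 at 0.64. Of 49 cytosolic ribosomal protein genes, 17 rose and none fell (17 and 0 adjusted over the list alone; median 0.16), with Rpl41 at 0.55, Rps29 at 0.52 and Rpl28 at 0.42 besides Rpl10a. Of 33 small nucleolar RNA genes, 26 fell and none rose (26 and 1 adjusted over the list alone; median -0.79), with Snord110 at -3.90, Snord87 at -2.84 and Snord111 at -2.79; their pull-down levels lay under the array medians, so these sizes are not exact. In camera (Benjamini-Hochberg) the adjusted p was 4.7e-11 for the respiratory chain, 6.7e-11 for ribosomal proteins and 1.6e-08 for small nucleolar RNAs, against adjusted p = 0.27, adjusted p = 0.25 and adjusted p = 0.25 with an estimated correlation. Of 10 mitochondrially encoded genes, 1 rose, ND6 at 1.19 (1 adjusted over the list alone; camera adjusted p = 0.02, and adjusted p = 0.48 with an estimated correlation). Of 10 nuclear long noncoding RNA genes, 5 fell and 1, Pantr1 at 0.41, rose (6 and 2 adjusted over the list alone; camera adjusted p = 0.42), with Snhg14 at -0.60 and Rian at -0.53. Of these noncoding RNAs 2 were higher and 2 lower with each array centred. Of 25 olfactory receptor genes, which are not expected in cortex, 5 were higher (3 adjusted over the list alone; median 0.09; camera adjusted p = 0.0001, and adjusted p = 0.34 with an estimated correlation). Of 7 replication-dependent histone genes, 3 rose and 1 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.025, and adjusted p = 0.34 with an estimated correlation). With each array centred 32 respiratory chain, 28 ribosomal protein, 6 mitochondrially encoded, 9 olfactory receptor and 3 histone genes were higher and none lower, and 22 small nucleolar RNAs were lower and 1 higher.

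The counts of receptor, channel and guidance transcripts, like those of other lists, depended on the scaling. Of 21 monoamine and acetylcholine receptor genes, 13 fell and 1 rose (13 and 1 adjusted over the list alone; 6 lower and 3 higher with each array centred), among them the serotonin receptor gene Htr2c at -0.97. Of 21 glutamate receptor genes, 11 fell and 1 rose (12 and 1 adjusted over the list alone; 7 lower and 1 higher with each array centred), with Grin3a at -0.74 and Grik1 at -0.61. Of 40 axon guidance genes, 23 fell and none rose (25 and 2 adjusted over the list alone; 7 lower and 4 higher with each array centred). The camera adjusted p was 0.049 for the monoamine and acetylcholine receptors, 0.045 for glutamate receptors and 0.025 for axon guidance, and adjusted p = 0.44, adjusted p = 0.44 and adjusted p = 0.48 with an estimated correlation. All of these calls were lost without the second NAC input (adjusted p = 0.0902, 0.0815 and 0.0563), and the first pair also without 4 other arrays. Of 11 GABA receptor genes, 7 fell (7 adjusted over the list alone; 5 lower and 2 higher with each array centred; camera adjusted p = 0.068), with Gabra2 at -0.70. Of 27 potassium and HCN channel genes, 2 rose and 11 fell (2 and 12 adjusted over the list alone; camera adjusted p = 0.42). With each array centred the split of these channels turned round, to 5 higher and 2 lower. Of 24 sodium and calcium channel genes, 3 rose and 7 fell (3 and 7 adjusted over the list alone; camera adjusted p = 0.54), and with each array centred the median of -0.12 was 0.02, with 3 higher and 1 lower. Of 26 synaptic vesicle genes, 8 fell (8 adjusted over the list alone; camera adjusted p = 0.54), with a median of -0.11 that was 0.03 with each array centred, where 4 were higher and 3 lower. Of 21 postsynaptic scaffold genes, 1 rose and 6 fell (1 and 6 adjusted over the list alone); their median was -0.06, camera ranked them upward (adjusted p = 0.79), and with each array centred 7 were higher and 1 lower. Of 22 neuropeptide genes, 5 rose and 6 fell (5 and 6 adjusted over the list alone; median -0.02, camera upward, adjusted p = 0.35, and with each array centred median 0.11, 6 higher and 4 lower), with Vgf at 0.66 and Vip at -0.41. Of 23 immediate early genes, 4 rose and 3 fell (4 and 3 adjusted over the list alone; median 0.02, mean -0.01; camera adjusted p = 0.066), and with each array centred 9 were higher and 2 lower. Of 19 interferon and antigen presentation genes, 1 rose and 11 fell (1 and 11 adjusted over the list alone; 1 and 5 with each array centred; camera adjusted p = 0.25). Of 18 heat shock and unfolded protein genes, 3 rose and 3 fell (3 and 3 adjusted over the list alone; median -0.05, camera upward, adjusted p = 0.31, and with each array centred median 0.08, 5 higher and 1 lower).

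**Figure D1:**
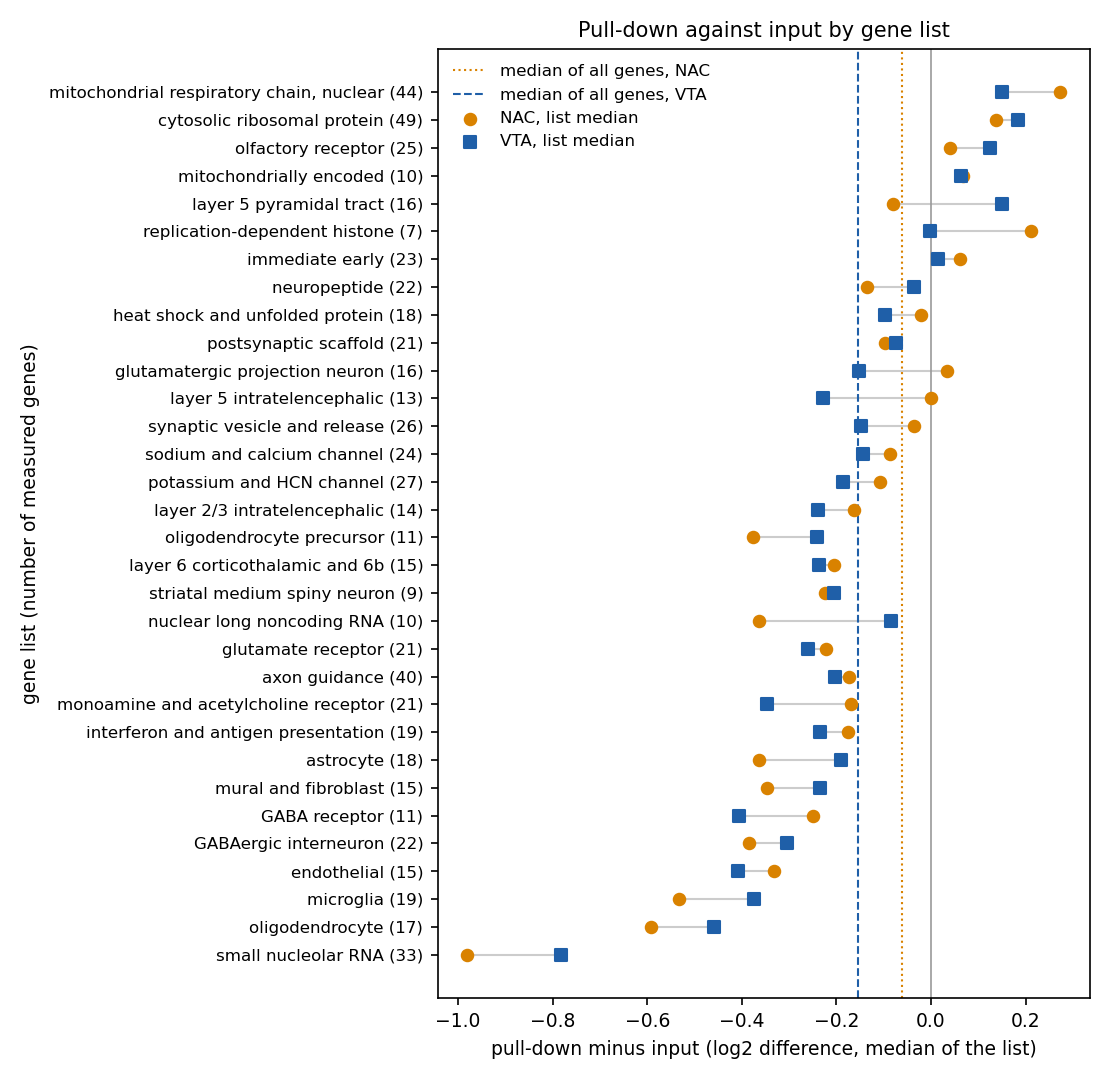
Median pull-down minus input difference (log2, horizontal axis) of each gene list, for NAC (orange circles) and VTA (blue squares) samples, with the medians of all genes drawn as vertical lines at -0.06 and -0.15. Oligodendrocyte (-0.59 and -0.46), microglial (-0.53 and -0.37) and small nucleolar RNA (-0.98 and -0.78) lists lie far left of those lines for both targets, and layer 5 pyramidal tract markers lie at -0.08 for NAC and 0.15 for VTA; with each array centred on its median all lists move to the right.

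Of 11712 genes, 4866 differed between pull-down and input in limma (Benjamini-Hochberg), 1124 higher and 3742 lower, and 8 of the higher and 26 of the lower differed at least 2-fold. This split depended on the scale of the arrays. The median of all genes was -0.11 with the deposited values and 0.03 when each array was centred on its median. Centring gave 2498 higher and 1753 lower genes, whereas quantile normalization gave 2060 and 2180. Enrichment here is therefore relative to that shift, and the count was 3068 without the first VTA input and 3160 without the first NAC input. Camera called 17 of the 32 lists with the preset correlation and 0 with an estimated one, and fry found 25 whose genes moved on balance one way.

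**Figure D2:**
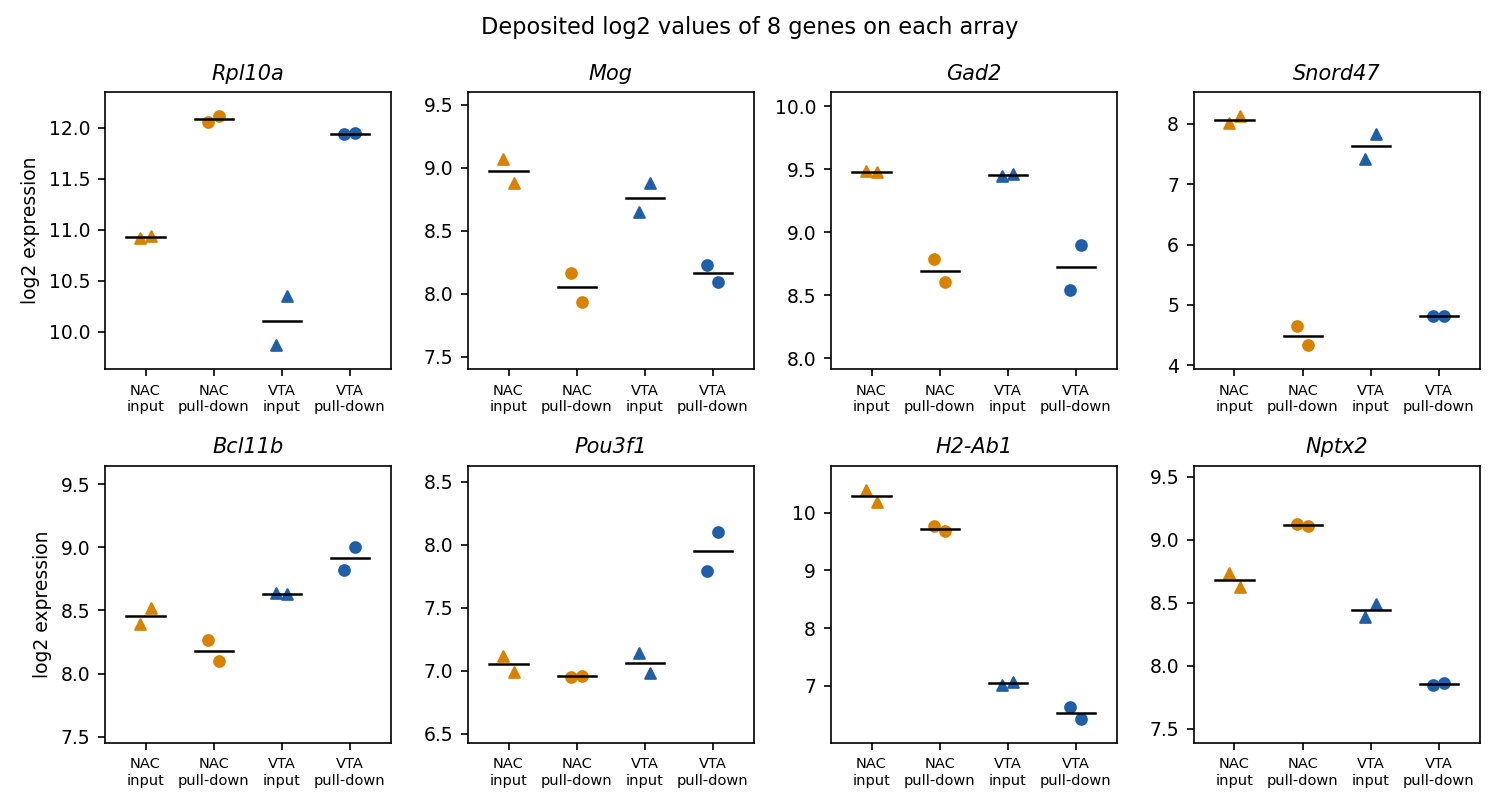
Values of 8 genes on each of the 8 arrays (log2, vertical axis), grouped by target and by pull-down or input; points are arrays and bars are means of 2 arrays. Rpl10a is highest in the pull-downs, Mog, Gad2 and Snord47 are lowest there, Bcl11b (8.91 ± 0.13, SD) and Pou3f1 (7.95 ± 0.22, SD) are highest in the VTA pull-downs, and H2-Ab1 is higher in both kinds of NAC sample.

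The same comparison was made within each target. In cells labelled from NAC, the pull-downs were higher than their inputs for the actin-binding muscle gene Xirp2 at 1.17 (SE 0.10, n = 2 and 2), for Dynlrb2, which codes for a dynein light chain, by an amount that is not exact because its input level lay under the array medians, and for the myosin light chain gene Myl6 at 1.12. The others were Tma7 at 1.36, Nol8 at 1.19, Rpl10a at 1.15, Mrpl54 at 1.08, Mrpl42 at 0.97, the RNA-binding gene Lsm3 at 0.97 and the tubulin chaperone gene Tbca at 0.95. They were lower for Ptcd3 at -2.51, the small RNAs Rny3 (-1.93), Scarna10 (-1.50), Rny1 (-1.44) and Scarna6 (-1.27). Also lower were the immunoglobulin genes Igkv8-30 (-1.33) and Ighg3 (-1.27), Eif4a1 (-1.24), Casp8 (-1.10) and Sft2d2. The second probe sets of Ptcd3 and Eif4a1 were at 0.21 and 0.19. Pull-down levels of Igkv8-30, Ighg3 and Scarna6 lay under the array medians, as did those of H60b with VTA and the VTA input level of Peg12, so these sizes are not exact. In cells labelled from VTA, the largest rises were Rpl10a at 1.83 (SE 0.14, n = 2 and 2), the mitochondrial gene ND6 at 1.79, Ywhah at 1.67, Mettl7a3 at 1.67 and Tuba1b at 1.42. Next came Tma7 at 1.25, Tpt1 at 1.16 (0.16 with its second probe set), the circular RNA host Cdr1 at 1.11, Atp5d at 1.11 and the imprinted gene Peg12 at 1.09. The largest falls were Casp8 at -1.47, Scarna10 at -1.35, Taf1d at -1.27, Creg1 at -1.25, Dapp1 at -1.24. They were followed by Htr2c at -1.22, Gpr52 at -1.20, Gjc3 at -1.18, Napepld at -1.18 and H60b at -1.17. The limma adjusted p (Benjamini-Hochberg) ran from 0.00038 for Xirp2 to 0.023 for Igkv8-30 among the NAC genes, and from 0.00026 for Rpl10a to 0.013 for Tpt1 among the VTA genes.

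Oligodendrocyte and microglial genes were depleted with both targets. Among oligodendrocyte genes, 14 of 17 fell in the NAC pull-downs (median -0.59; 15 adjusted over the list alone) and 14 of 17 in the VTA pull-downs (median -0.46; 14 adjusted over the list alone). Among microglial genes, 15 of 19 fell with NAC (19 adjusted over the list alone) and 10 of 19 with VTA (12 adjusted over the list alone). Over the settings tried, the VTA medians came as near 0 as -0.26 for oligodendrocytes and -0.18 for microglia. Among small nucleolar RNAs 20 of 33 fell with NAC (26 adjusted over the list alone) and 21 with VTA, where 1 rose (the same counts adjusted over the list alone). The camera adjusted p for oligodendrocytes was 4.0e-10 with NAC and 0.00021 with VTA, and adjusted p = 0.11 and adjusted p = 0.36 with an estimated correlation. Other glia were called with NAC only. Astrocyte genes fell in 10 of 18 cases with NAC (12 adjusted over the list alone; camera adjusted p = 1.4e-06, and adjusted p = 0.20 with an estimated correlation) and in 6 of 18 with VTA (6 adjusted over the list alone; camera adjusted p = 0.24). With each array centred the astrocyte medians were -0.29 with NAC and 0.00 with VTA. Oligodendrocyte precursor genes fell in 6 of 11 cases with NAC (7 adjusted over the list alone; camera adjusted p = 0.0013, and adjusted p = 0.14 with an estimated correlation) and in 5 of 11 with VTA (5 adjusted over the list alone; camera adjusted p = 0.43). Over the settings tried, the VTA median of the precursor list ran from -0.45 to -0.04. In the difference of enrichment camera ranked both lists upward (astrocyte median 0.18, adjusted p = 3.8e-05; oligodendrocyte precursor median 0.14, adjusted p = 0.0026), but both calls were lost with adjusted p = 0.22 with an estimated correlation and no gene of either list passed. Layer 5 pyramidal tract genes showed no direction with NAC, where 2 rose and 3 fell (3 and 4 adjusted over the list alone; median -0.08, camera adjusted p = 0.72) and, with each array centred, 3 were higher and 1 lower. With VTA 5 rose and 1 fell (5 and 1 adjusted over the list alone; median 0.15, camera adjusted p = 6.0e-06, and adjusted p = 0.30 with an estimated correlation). In the VTA pull-downs Chst8 rose by 1.02, Pou3f1 by 0.89, Fezf2 by 0.51 and the neurofilament gene Nefm by 0.46. For replication-dependent histone genes with VTA the median of -0.00 and the upward camera call (adjusted p = 0.04, and adjusted p = 0.47 with an estimated correlation) differed in sign.

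In limma (Benjamini-Hochberg), 1446 genes passed with NAC (508 higher, 938 lower) and 3671 with VTA (637 higher, 3034 lower). With each array centred these were 905 higher and 643 lower for NAC and 1719 and 1083 for VTA. The comparisons share no arrays, and 245 genes rose in both, against 27.6 if the lists were independent, while 698 fell in both, against 243. Fisher's exact test, which asked only for a larger overlap, gave p = 1.0e-185 and p = 8.5e-234. The comparisons do share 1 estimate of each gene's spread, and the test takes genes as independent, so these p-values are too small. The log2 differences correlated across genes with Pearson's r = 0.694 and Spearman's rho = 0.668, although genes are not independent replicates. The larger count with VTA is not a test of a difference between targets. The NAC count was 177 without the second NAC pull-down, 149 and 157 without the first and second NAC input, and 863 without either VTA input. The VTA count was 415 without the first VTA input, 1941 without the second and 1795 without the first VTA pull-down. ND6, Ywhah, Tuba1b, Tpt1, Cdr1, Atp5d, Dapp1, Gpr52, Taf1d and Fezf2 all lost their VTA call without the first VTA input, Fezf2 at 0.55 (adjusted p = 0.0511).

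The pull-downs were then compared with each other, to ask how ribosome-bound RNA differed between mPFC cells labelled from VTA and from NAC. Pull-down RNA also held transcripts of other cells, since the oligodendrocyte and microglial lists had medians of only -0.48 and -0.46 against input. A difference between pull-downs therefore need not lie in the labelled cells. Immune genes were far lower in the VTA pull-downs. H2-Ab1, which codes for a class II antigen-presenting chain, was 9.08-fold lower (log2 difference -3.18, SE 0.11, n = 2 and 2; 9.72 ± 0.07 with NAC and 6.54 ± 0.15 with VTA, SD). The immunoglobulin segment Igkv9-120 was also lower (7.28 ± 0.55 with NAC and 2.92 ± 0.18 with VTA), by an amount that is not exact because its VTA level lay under the array medians. Of the layer 5 pyramidal tract markers, the transcription factor genes Pou3f1 and Bcl11b were higher in VTA by 0.99 (SE 0.12) and 0.73 (SE 0.11), and the sulfotransferase gene Chst8 by 0.88 (SE 0.11). Tcerg1l, which is on the layer 5 intratelencephalic list, had the largest rise among genes that passed, 1.22 (SE 0.11; 6.83 ± 0.16 with NAC and 8.06 ± 0.07 with VTA). The limma adjusted p (Benjamini-Hochberg) was 4.3e-06 for Igkv9-120, 6.6e-07 for H2-Ab1, 0.00021 for Tcerg1l, 0.0014 for Pou3f1, 0.005 for Bcl11b and 0.0015 for Chst8.

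Other large falls were those of the class II gene H2-Aa (-2.98), the interferon-induced GTPase genes Igtp (-2.76) and Gbp10 (-2.44), the chemokine genes Ccl5 (-2.75), Cxcl9 (-2.47) and Cxcl10 (-2.44), and the immunoglobulin segment Igkv6-14. The VTA levels of H2-Aa, Igtp, Cxcl9 and Cxcl10 lay under the array medians, as did all levels of Igkv6-14 in these groups, so the sizes of those falls are not exact. Other rises were those of Rny3 (0.95), Trmt9b (0.90), Doc2b, a calcium sensor of vesicle release (0.88), Rny1 (0.88), the natriuretic peptide receptor gene Npr3 (0.79) and Igfbp4 (0.77). Of 16 layer 5 pyramidal tract genes, 7 rose and none fell (9 and 2 adjusted over the list alone; median 0.38), including Parm1 at 0.72, Bcl6 at 0.69 and Fezf2 at 0.51 besides Pou3f1, Bcl11b and Chst8. Pcp4 (-0.36) and S100a10 (-0.32), also on this list, did not pass over all genes. Camera ranked the list upward (Benjamini-Hochberg adjusted p = 9.8e-11, and adjusted p = 0.12 with an estimated correlation). Of 13 layer 5 intratelencephalic genes only Tcerg1l passed (1 higher and 1 lower adjusted over the list alone); their median was -0.13, their mean -0.01, and camera ranked them upward (adjusted p = 0.94). Fezf2 lost its call without the first NAC pull-down (0.43, adjusted p = 0.15) or the second VTA pull-down (0.47, adjusted p = 0.0724). Bcl11b lost its call in a fit on only these groups (adjusted p = 0.0539). Without 1 array, Rny3, Rny1, Trmt9b and Doc2b also lost theirs. Examples are Rny1 without the first NAC pull-down (0.73, adjusted p = 0.103), Rny3 without it (adjusted p = 0.122), and Trmt9b and Doc2b without the second NAC pull-down (adjusted p = 0.0854 and 0.0987).

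Of 19 interferon and antigen presentation genes, 17 fell (19 adjusted over the list alone; median -1.41), with Ifit1 at -1.90, H2-K1 at -1.60, Ifitm3 at -1.45 and Tap1 at -1.30. Camera gave a Benjamini-Hochberg adjusted p of 1.4e-35, and the call held with adjusted p = 0.0073 with an estimated correlation. Of 19 microglial genes, 9 fell and 1, Fcrls at 0.71, rose (12 and 1 adjusted over the list alone; median -0.36; camera adjusted p = 2.5e-08, and adjusted p = 0.13 with an estimated correlation), with the lysosomal protease gene Ctss at -1.02 and the complement gene C1qa at -0.83. Markers such as Cx3cr1 (-0.17), P2ry12 (-0.17) and Tmem119 (0.08) did not pass. Of 23 immediate early genes, which respond to neuronal activity, 6 fell (10 adjusted over the list alone; median -0.22; camera adjusted p = 2.4e-06, and adjusted p = 0.19 with an estimated correlation). Npas4 was at -1.38, Fos at -1.07 and Arc at -0.92. Nptx2, which codes for a secreted synaptic pentraxin, was at -1.26. Fos lost its call without the first VTA pull-down (-0.96, adjusted p = 0.0562). Gfap, an intermediate filament gene of astrocytes, fell by 1.22 while the astrocyte list had a median of 0.18 (1 of 18 fell, and 1 adjusted over the list alone; camera adjusted p = 0.00018 upward, and adjusted p = 0.22 with an estimated correlation). Ptprc fell by 0.81. Slc17a7 (-0.22), Camk2a (0.02), Drd1 (-0.00) and Rpl10a (-0.14) did not pass.

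Several lists were called by camera with no or few members past the threshold: GABAergic interneurons (median 0.15, 0 of 22; 0 adjusted over the list alone), oligodendrocyte precursors (median 0.12, 0 of 11; 3 higher adjusted over the list alone), small nucleolar RNAs (median 0.23, 3 of 33 higher; 4 adjusted over the list alone) and glutamatergic projection neurons (median -0.15, 0 of 16; 1 lower adjusted over the list alone). Their camera adjusted p-values (Benjamini-Hochberg) were 3.8e-05, 0.00028, 3.8e-05 and 0.049, and adjusted p = 0.19, adjusted p = 0.15, adjusted p = 0.19 and adjusted p = 0.21 with an estimated correlation. The same held, all upward, for the layer 6, striatal, endothelial, glutamate receptor, sodium and calcium channel, postsynaptic scaffold and neuropeptide lists, whose camera adjusted p-values lay between 0.016 and 0.042 and whose values ran from adjusted p = 0.19 to adjusted p = 0.52 with an estimated correlation. The call of glutamatergic projection neurons was past the threshold in only 4 of 16 other settings and that of striatal neurons in 8 of 16. Both were lost without any 1 of the 4 pull-down arrays, with the highest adjusted p = 0.195 for glutamatergic projection neurons (without the second VTA pull-down). The glutamate receptor, postsynaptic scaffold and endothelial calls held in 10, 11 and 12 of 16 settings. Single members of lists that passed were the neuropeptide gene Adcyap1 (0.70), the axon guidance genes Robo1 (0.63) and Efna3 (-0.57), the calcium channel gene Cacna1h (0.52) and the noncoding RNA gene Snhg11 (0.53).

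In limma (Benjamini-Hochberg), 289 genes differed between the pull-downs, 49 higher and 240 lower in VTA, with 1 and 73 of them at least 2-fold. Centring each array gave 96 higher and 196 lower, and the count was 151 without the first NAC pull-down. Camera called 16 of 32 lists, 1 of them with an estimated correlation, and fry called 6.

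The inputs gave the same comparison in unpurified mPFC RNA, as the background of the pull-downs. Immune genes were again far lower in VTA samples, at -3.25 for H2-Ab1 (SE 0.11, n = 2 and 2; 10.29 ± 0.15 with NAC and 7.04 ± 0.04 with VTA, SD). Igkv9-120 was at 8.20 ± 0.08 with NAC and at 3.33 ± 0.02 with VTA, which is under the array medians. The largest falls besides these included the interferon-induced GTPase gene Igtp (-2.84), Ccl5 (-3.08) and H2-Aa (-2.89). Igkv8-30, Igkv6-14, the GTPase gene Iigp1 and Jchain, which codes for the joining chain of secreted antibodies, also fell, to VTA levels under the array medians, so the sizes of their falls are not exact. Only 14 genes were higher in VTA inputs, led by Tnnc1, a troponin gene also placed among layer 5 markers, at 1.02 (SE 0.11). The others named here were Fcrls (0.71), the glycine receptor gene Glra3 (0.64), the noncoding RNA gene Rmst (0.59), Actn2 (0.58), the retinoic acid synthesis gene Aldh1a2 (0.56), Mcm3ap (0.56), Rpap2 (0.52) and Glt8d2 (0.52). The limma adjusted p (Benjamini-Hochberg) was 1.4e-06 for Igkv9-120, 5.4e-07 for H2-Ab1 and 0.00046 for Tnnc1.

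Of 19 interferon and antigen presentation genes, 16 fell in the VTA inputs (18 adjusted over the list alone; median -1.35; camera with Benjamini-Hochberg adjusted p = 1.5e-58, and adjusted p = 0.0027 with an estimated correlation). Of 19 microglial genes, 10 fell and 1 rose (15 and 1 adjusted over the list alone; median -0.54; camera adjusted p = 6.3e-27, and adjusted p = 0.021 with an estimated correlation), with Fcer1g at -1.29 and Ctss at -1.26. Of 23 immediate early genes, 5 fell (13 adjusted over the list alone; median -0.31; camera adjusted p = 3.0e-15, and adjusted p = 0.11 with an estimated correlation), with Npas4 at -1.23, Fos at -0.92, Arc at -0.85, Egr2 at -0.73 and Junb at -0.62. Of 16 layer 5 pyramidal tract genes none passed (0 adjusted over the list alone; median 0.08; camera adjusted p = 0.70); Pou3f1 was at 0.01, Fezf2 at -0.03, Chst8 at 0.16 and Bcl11b at 0.18. Gfap was at -0.83, Ptprc at -0.97, the fibroblast collagen gene Col1a1 at -0.71 and Malat1, a nuclear noncoding RNA, at -0.47, and all passed. Rpl10a fell by 0.82 (limma adjusted p with Benjamini-Hochberg = 0.0133), a call lost without the first VTA input (-0.58, adjusted p = 0.0785), the first NAC input (adjusted p = 0.106) or the second NAC input (adjusted p = 0.145). The call of Fos was lost without the second NAC input (adjusted p = 0.194) or either VTA input (adjusted p = 0.347 and 0.123).

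**Figure D3:**
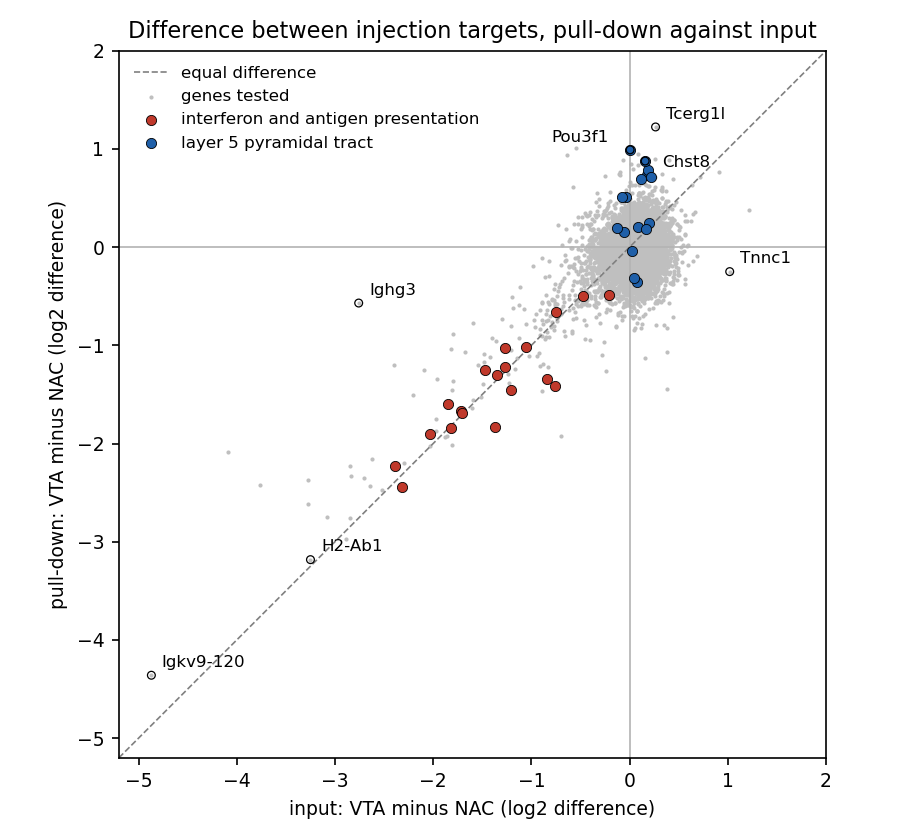
Difference between VTA and NAC (log2) in the inputs (horizontal axis) and in the pull-downs (vertical axis), with 1 point per gene; interferon and antigen presentation genes are red, layer 5 pyramidal tract genes are blue, and the dashed line marks equal differences. Interferon genes lie along the dashed line, with medians of -1.35 and -1.41, and layer 5 pyramidal tract genes lie above it, with medians of 0.08 and 0.38.

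In limma (Benjamini-Hochberg), 176 genes differed between the inputs, 14 higher and 162 lower in VTA. Of the genes lower in VTA pull-downs and inputs, 126 were shared, against 3.32 if the lists were independent, and 3 of the higher genes were shared, against 0.06. Fisher's exact test, which asked only for a larger overlap, gave p = 6.9e-195 and p = 2.4e-05. These comparisons share no arrays but do share 1 estimate of each gene's spread, and the test takes genes as independent, so the p-values are too small. Across all genes the log2 differences correlated with Pearson's r = 0.52 and Spearman's rho = 0.133, although genes are not independent replicates. Of the 176 genes, 170 had the same sign in the pull-downs, with medians of -0.89 in inputs and -0.78 in pull-downs, and 2 passed the test of the difference between those comparisons. Of the 289 pull-down genes, 160 did not pass in the inputs, 46 of them higher and 114 lower in VTA. The count was 109 without the second NAC input, 102 without the first VTA input and 100 without the second. Further lists called by camera in the inputs had small shifts. They were layer 5 intratelencephalic (median 0.10, adjusted p = 0.025), oligodendrocyte (-0.10, adjusted p = 0.0058), respiratory chain (-0.02, adjusted p = 0.019), ribosomal protein (-0.05, adjusted p = 0.0017), nuclear noncoding RNA (-0.08, adjusted p = 0.0058) and olfactory receptor genes (-0.07, adjusted p = 0.0058). None held, with values from adjusted p = 0.27 to adjusted p = 0.75 with an estimated correlation.

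The difference of enrichment asked whether pull-down and input differed by another amount in VTA than in NAC samples. Xirp2 rose in the NAC pull-downs from 7.29 ± 0.06 to 8.46 ± 0.07 and fell in the VTA pull-downs from 7.68 ± 0.07 to 7.02 ± 0.08 (log2 mean ± SD, n = 2). The difference was -1.83 (SE 0.14). Lower enrichment in VTA samples was also found for Tnnc1 (-1.27), the acrosomal gene Dkkl1 (-1.15), Nptx2 (-1.02), Gm10139 (-1.21) and 1700007K13Rik (-0.91). The immunoglobulin gene Ighg3 passed in the other direction, but only its NAC input level (6.08 ± 0.09) lay above the array medians and the other levels were 3.33 to 4.81, so no enrichment can be read from it. Dynlrb2 passed as well, but of its levels only that of the NAC pull-downs (6.47 ± 0.23) lay above the array medians, so the size of its difference is not exact. The limma adjusted p (Benjamini-Hochberg) was 0.00116 for Xirp2, 0.0251 for Dynlrb2, Tnnc1 and Dkkl1, and 0.0323 for Nptx2 and Ighg3. Of 16 layer 5 pyramidal tract genes none passed over all genes, and 8 were higher and 1 lower adjusted over the list alone (median 0.41; camera with Benjamini-Hochberg adjusted p = 2.0e-09, and adjusted p = 0.20 with an estimated correlation). Among them Pou3f1 (0.98, adjusted p = 0.128), Fezf2 (0.54, adjusted p = 0.26) and Bcl11b (0.55, adjusted p = 0.272) missed the limma threshold, as did Tcerg1l (0.96, adjusted p = 0.12), Igfbp4 (0.86, adjusted p = 0.0849), Clec7a (adjusted p = 0.0526, with 3 of its 4 levels under the array medians) and Rpl10a (0.68, adjusted p = 0.272). Of the interferon genes none passed (0 adjusted over the list alone; median 0.03, mean -0.05; camera adjusted p = 0.33). Of 11712 genes, 8 passed, 1 higher and 7 lower, and 6 passed with each array centred, 2 higher and 4 lower. With all probe sets tested singly, 9 probe sets were higher and 2 lower. This setting includes probe sets without a single gene name, so it does not show that the same genes changed direction. With the replicate number as a block, or with pull-down and input as pairs, only Xirp2 passed (limma with Benjamini-Hochberg adjusted p = 0.0038 and 0.0126). The calls of the other 7 genes were lost in both, for example Dynlrb2 (adjusted p = 0.0682 and 0.0505) and Nptx2 (adjusted p = 0.0792 and 0.0822). The count was 8 without the second VTA pull-down and between 1 and 5 without any other array. It was 4 and 5 without the first and second NAC pull-down, 1 without either NAC input, the first VTA pull-down or the first VTA input, and 2 without the second VTA input.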

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

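The split of the arrays, the calls of the difference of enrichment, the other scalings and the leaving out of arrays were planned; the tests that set explanations against each other were chosen only after the result they concern had been seen. All 35 ways to split the 8 arrays into 4 and 4 were fitted, and the split into pull-downs and inputs gave 3847 genes, the most of any; 1 of the 35 reached that count, and the next highest, the split by injected target, gave 103.

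Immune genes were lower in VTA than in NAC samples in pull-downs and inputs alike. Lymphocytes in the tissue stay open as the cause. T and B lymphocyte markers had a median of -1.20 between the inputs, with 9 of 11 lower in VTA and 0 higher. Of the 11 markers 3 were already named for a large change and 8 lay under the array median in at least 1 group, which left 2. These were Ighm, which was lower in the VTA inputs by 0.70, and Cd6, which did not pass (-0.04). A level under the median in VTA samples alone is also what lymphocytes present mainly in NAC tissue would give. Cd3e was at 7.51 in NAC and 5.70 in VTA inputs, and Cd8b1 at 6.33 and 5.13, with both VTA levels under the array medians. Most of the markers thus go with more lymphocyte RNA in the NAC inputs, but Cd6 and Icos (-0.27) did not pass, and the 2 markers left disagree. Whether lymphocytes account for the other immune genes was not tested. The interferon list had a median of -1.29 in the weakest of 3 other scalings and -1.35 in the deposited values. The arrays already shared a scale (medians over all probe sets 5.08 to 5.22), so rescaling could move the list only little. This test could hardly have come out otherwise, and shows only that these scalings left the difference in place. Carry-over of unpurified RNA stays open. In the NAC pull-downs the interferon list was 0.157 above the least depleted glial or vascular list, the endothelial one (permutation p = 0.114). That permutation took genes as independent and did not use the spread between arrays. A batch of animals or surgery that coincides with the injected target cannot be told apart from the target; the largest median difference between replicates over the list was 0.185, and close replicates are what such a batch would give too.

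Layer 5 pyramidal tract markers were higher in the VTA pull-downs. The list mean per array gave a difference of enrichment of 0.31 (SE 0.05 over arrays; median over genes 0.41), which speaks against a different make-up of the dissected tissue as the whole cause, although camera lost the list with adjusted p = 0.20 with an estimated correlation and no member passed over all genes. In the pull-downs the list lay above glutamatergic markers by 0.51 (SE 0.02 over arrays, medians 0.522 apart). This cannot decide on higher purity, since glutamatergic markers did not rise from input to pull-down (median -0.06, both targets averaged). Glial lists were not more depleted with VTA than with NAC (oligodendrocyte medians -0.46 and -0.59, microglia -0.37 and -0.53). Endothelial medians were -0.41 with VTA and -0.33 with NAC, but the medians of all genes also differed (-0.15 and -0.06). The endothelial median difference of enrichment was -0.02, so this list was not shown to be more depleted with VTA either. The lowest median of the pyramidal tract list with 1 array left out was 0.325, against a single array. As a hypothesis, a larger share of pyramidal tract cells among cells labelled from VTA could account for it, since the list lay 0.45 (SE 0.02 over arrays; medians 0.552 apart) above the intratelencephalic lists in the difference of enrichment. A batch cannot be told apart from the target here either, and the largest median difference between replicates over the list was 0.119.

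Rpl10a stood far above its input in the pull-downs. It exceeded the next highest ribosomal protein gene by 0.887, which is against the general rise of ribosomal protein transcripts as the whole cause of its value. That next gene, Rps28, was at 0.605 and the median of the other 48 was 0.16. As a hypothesis, the probe set could also read a transcript of a tagged ribosomal protein made in the labelled cells; which ribosomal protein carries the tag is not given in the sources used here.

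Other values stood out because a comparison between the targets, with the inputs subtracted, passed. The genes were Xirp2 (-1.83), Dynlrb2 (-1.45), Tnnc1 (-1.27), Gm10139 (-1.21), Dkkl1 (-1.15), Nptx2 (-1.02), 1700007K13Rik (-0.91) and Ighg3 (2.19). For Ighg3 only the NAC inputs and for Dynlrb2 only the NAC pull-downs lay above the array medians, so the value of Ighg3 does not show enrichment and the size for Dynlrb2 is not exact. The lists called by camera, by their median difference of enrichment, were layer 5 pyramidal tract (0.41), nuclear long noncoding RNA (0.27), astrocyte (0.18), oligodendrocyte precursor (0.14), olfactory receptor (0.14), microglia (0.10), small nucleolar RNA (0.10), GABAergic interneuron (0.08), layer 6 (0.08), oligodendrocyte (0.08), neuropeptide (0.05), mural and fibroblast (0.04) and cytosolic ribosomal protein (0.03). None of these 13 calls held with an estimated correlation, where the lowest was adjusted p = 0.20. The median turned below 0 without the second NAC pull-down for layer 6 (-0.04), without the first NAC input for neuropeptides (-0.01), without the first VTA pull-down (-0.02) or the second VTA input (-0.01) for olfactory receptors, and without the first VTA input for ribosomal proteins (-0.05) and small nucleolar RNAs (-0.01). The layer 6 and neuropeptide calls held in 10 of 16 other settings each and the mural and fibroblast call in 8 of 15. Among 4646 probe sets without a single gene name, 101 passed between the pull-downs, 26 higher and 75 lower in VTA, and they were not analysed here further.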

How the results depend on the processing

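The counts were 4866 (averaged pull-down against input), 1446 (NAC), 3671 (VTA), 289 (between pull-downs), 176 (between inputs) and 8 (difference of enrichment). Quantile normalization gave 2 for the difference of enrichment, and normalizing pull-downs and inputs apart gave 2451 for NAC. Without the filter the NAC, VTA, pull-down and difference counts were 105, 1907, 113 and 1, and above the 75th percentile the averaged, VTA, input and difference counts were 2849, 2317, 44 and 14. Trend and robust moderation gave 550 between pull-downs and 29 for the difference. Without moderation the 6 counts were 2489, 36, 696, 30, 21 and 0; beside that 0 in limma, 1409 genes had an unadjusted p under 0.05 for the difference in the moderated fit. A fit on only the groups compared gave 119 between pull-downs. At least 2-fold with an unadjusted p under 0.05 left 34, 39, 84, 77, 77 and 17, and an adjusted p of 0.10 gave 2523 for NAC and 529 between pull-downs. Leaving out the genes past the threshold in the inputs, chosen after seeing the data, gave 72 between pull-downs. The cause of these moves was not tested.

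With the replicate number as a block, or with pull-down and input as pairs, the difference of enrichment gave 1 gene each; crossed pairing, chosen after seeing the data, gave 442 between pull-downs. Correlations of replicate differences for the same number ran from -0.13 to 0.30 between groups, so the numbers are not shown to pair.

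With 1 array left out the averaged count ran from 3068 (without the first VTA input) to 5065, NAC from 149 (without the first NAC input) to 1848, VTA from 415 (without the first VTA input) to 3713, pull-downs from 151 (without the first NAC pull-down) to 335, inputs from 100 (without the second VTA input) to 206, and the difference from 1 (without either NAC input, the first VTA pull-down or the first VTA input) to 8. Counts also moved more than 1.5-fold without the first NAC input (averaged, 3160), the second NAC input (NAC, 157; inputs, 109), the second NAC pull-down (NAC, 177; difference, 5), the first NAC pull-down (difference, 4), either VTA input (NAC, 863), the first VTA pull-down (VTA, 1795), the second VTA input (VTA, 1941; difference, 2) and the first VTA input (inputs, 102). These fits pool the spread, and the lone array of a group is assumed to vary like the other groups. Of 4396 values of named genes 4053 stayed on the same side of the threshold, whether called or not, 305 were weaker, 38 stronger and 0 reversed. Of 1450 values of called lists 1169 kept their call and 281 were weaker. Among these, 162 values came from the other set tests, of which 47 kept the call and 115 were weaker. With 2 arrays per group, small differences could not be measured well.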

Other observations

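Gene families beyond the lists were looked at only after the data had been seen. In all of them but the complement genes some VTA pull-down levels lay under the array medians, among the GTPase genes all but that of Gbp10, so the sizes of their medians are not exact. Of 12 genes taken by symbols that start with H2-, most of them histocompatibility genes, 9 were lower in the VTA pull-downs (median -1.14) and 9 in the VTA inputs (median -1.19). Of 8 interferon-induced GTPase genes, all 8 were lower in both (medians -1.98 and -1.95). Of 11 immunoglobulin segments, 9 were lower in the pull-downs (median -2.08) and 11 in the inputs (median -2.76), and of 4 complement genes all 4 were lower in both (medians -0.80 and -0.90), with C4b at -2.20 and -2.30. Of 12 chemokine genes, 6 were lower and 1 higher in the pull-downs and 6 lower in the inputs.

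Clustered protocadherins, cell surface genes of neuronal self-recognition, were lower in the pull-downs: 13 of 16 in the averaged comparison (median -0.44) and 13 in VTA samples (median -0.61), against 1 in NAC samples (median -0.24), while none passed the test of the difference of enrichment (median -0.37). Over all 11712 genes, 3742 were lower in the averaged comparison, 3034 in VTA and 938 in NAC samples, so 13 against 1 is not a test of a difference between targets. The family was not counted with each array centred. Many VTA pull-down levels of these protocadherins also lay under the array medians. Of 6 small Cajal body and Y RNA genes, all 6 were lower in the pull-downs (median -0.90), 5 with NAC (median -1.35) and 4 with VTA (median -0.455). RNAs of this kind are not translated, and their loss sits beside that of small nucleolar RNAs.

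As a hypothesis, the immune genes and the immediate early genes are separate effects of the injected target or of the day of the experiment. Neither was separated here, and the replicates' largest median difference of 0.185 over the interferon list leaves a batch open. Slices or sorted cells from animals injected in NAC and others injected in VTA on the same day would separate target from day. They would not by themselves show that the immune and immediate early genes are separate effects. The pyramidal tract markers could be followed by counting labelled cells by layer, since their median stayed at or above 0.325 with any 1 array left out.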
